A study of Homo sapiens with 93 samples.

How the data were processed

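Host RNA in sonicate fluid, the liquid in which an explanted joint implant is sonicated, was sequenced in 93 libraries. The labels give each library the same source and no condition, so no library was placed in a group and no contrast between infected and other failed implants was made. The submitters' notes name TopHat2, featureCounts and the genome build hg38, without versions. The deposited table holds raw counts per gene with 1 column per library, together with gene symbols, positions and exon lengths. Of 20028 genes named once in both the table and the GENCODE annotation on GRCh38, 14.0% overlapped their GRCh38 position, so the coordinates in the table are not those of the build that the notes name. Positions below are therefore those of the deposited table, whose build is not stated in it. All deposited counts were even, as when both reads of a pair are counted, and exact intervals and floors were computed on read pairs. These intervals and floors cover counting error only. The columns of the table form 2 runs sorted by header, of 41 and 52 libraries, whose meaning is not stated, and no library was placed in a group by them. The table holds no mitochondrial chromosome and 0 spike-in rows.

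Of 23398 gene rows, 40 copies of another row were dropped, 118 rows were left out to keep personal detail out of the results, and 23240 were kept. Total counts ranged from 804962 to 13541372 (median 2371520, quartiles 1438012 and 3765544). Composition was described in all 93 libraries. All other results used the 88 libraries with at least 1000000 counts. A gene with no read pair has an upper limit of 5.97 CPM (counts scaled to the library total) in the shallowest of these 88 libraries and 0.443 CPM in the deepest, from 3 pairs. All 3828 pairs of the 88 libraries were compared for duplicates. The highest correlation was 0.960 and the lowest chi-square per degree of freedom was 3.74, far above the value near 1 that repeated counts of the same library would give.

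Counts were scaled by edgeR 4.0.16 (TMM factors from the 10879 genes that filterByExpr kept) and expressed as log2 CPM with a prior count of 2, in R 4.3.3. Before the data were examined, 413 genes were placed in 35 lists, 21 for cell types and 14 for pathways. Of these genes 404 were found, 7 of them under an older symbol. A member was measured if it reached 1 CPM in at least 10% of the libraries, and the score of a list is the mean log2 CPM of its measured members. Coherence is the mean pairwise correlation of the members, ranked among 1000 random lists matched on expression in 20 bins (1-sided, Benjamini-Hochberg adjusted over lists). Scores of 27 pairs of lists, fixed beforehand, were compared by Pearson's r and Spearman's rho. Each had a 2-sided permutation test with 100000 resamples, or exact enumeration below 10 libraries. Adjustment ran over the 42 tests that resulted, at a threshold of 0.05. The smallest p these permutations can give is 1e-05. Each r was repeated without the 2 libraries farthest from the median on the first score, and ranked among 1000 pairs of random matched lists. A score was read as falling into clusters if a mixture of 2 normal distributions gained more than 10 in BIC over 1 and Ashman's D exceeded 2. In that case no r over all libraries was computed, and r was given within clusters of at least 6 libraries. Bootstrap intervals (95%) used 2000 resamples.

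Named genes followed a rule fixed beforehand. It took the 25 genes with the highest median CPM, with mitochondrial, ribosomal RNA-like and ribosomal protein genes given as classes. It also took the 25 genes with the largest median absolute deviation (MAD, scaled to the SD of a normal distribution) of log2 CPM among those with a median of at least 10 CPM, and, in each list, the 3 most abundant members and the 1 other with the largest MAD. For the neutrophil receptor and macrophage scores it took the 10 genes outside the lists with the highest r and the 10 with the lowest, and for each of the first 2 principal components the 8 genes with the largest loadings in each direction. Examples from these were chosen for the text, and some genes that the rule takes are not reported here. Principal components used the 1000 most variable genes outside the lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

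Alternatives fixed beforehand were DESeq2 1.42.0 size factors, library totals only, no filter on low counts, median or summed CPM as the score, a depth minimum of 5000000 counts or none, thinning, partial correlation given depth and genes detected, the lower and upper part of the libraries by total counts, and totals without ribosomal RNA-like genes and globins. A set of 83 genes with 2 distinct levels was found on examining the data. Its members are the measured genes with r of at least 0.9 with S1PR2, a member noticed first. The definition was first applied to filtered genes only and was widened after first tests on the smaller set had been seen. Primary granule and nucleated erythroid lists for a closing test were also chosen after seeing the data. Repeating results within the levels of this set, with the level as a term, and without its genes, was chosen after seeing the data. The steps were tested on simulated data built from the 88 libraries. All 12 lists given a shared factor were called coherent and 0 of 12 others were. Of 200 genes given a slope, 73% were recovered at the smaller slope and 100% at the larger, and 0.0673% of genes without a slope were called. Apart from the planted factors, simulated genes varied independently with a common dispersion, without levels or runs of columns, and TMM was not applied. The rate of false calls in the simulation therefore need not hold in the libraries.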

Results

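The series measured human gene expression in sonicate fluid from resected implants after arthroplasty failure, and its title names the response to periprosthetic joint infection. All 93 libraries are unassigned: the labels separate no infected from uninfected implants, so values are given as medians, ranges and relations across libraries. Total counts had a median of 2371520 (range 804962 to 13541372). Relations were computed in the 88 libraries with at least 1000000 counts, leaving out the other 5. A median of 16682 genes had at least 1 count (range 10466 to 21471).

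The fluid held transcripts of phagocytes, stroma and blood. MALAT1, a nuclear noncoding RNA, was the most abundant transcript, with a median of 6.64% of counts (range 0.823 to 25.0%, exact 95% intervals of the extremes 0.801 to 0.847% and 24.9 to 25.1%). The 10 most abundant genes of each library together took a median of 16.5% of its counts (range 9.69 to 32.3%). Ferritin light chain FTL (chromosome 19, 49468566 to 49470136) had a median of 6236 CPM and ferritin heavy chain FTH1 (chromosome 11, 61731757 to 61735132) 4696 CPM. Fibronectin FN1 had a median of 5589 CPM, the collagen gene COL1A1 3533 CPM and COL3A1 1882 CPM. SPP1, which encodes osteopontin, had 2888 CPM, and LRP1, an endocytic receptor, 2035 CPM. Collagen I and III genes together ranged from 0.00624 to 6.63% of counts (median 0.739%). Globin genes ranged from 0.00208 to 10.4% (median 0.215%), ribosomal protein genes from 0.230 to 3.61% (median 1.69%) and mitochondrial rRNA-like genes from 0.0526 to 6.17% (median 0.602%). Exact 95% intervals of the lowest and highest shares were 0.00517 to 0.00748% and 6.60 to 6.66% for collagens, 0.00147 to 0.00286% and 10.3 to 10.5% for globins, 0.223 to 0.237% and 3.57 to 3.66% for ribosomal proteins, and 0.0494 to 0.0560% and 6.11 to 6.23% for mitochondrial rRNA-like genes.

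Part of the counts came from a set of 83 genes on 21 chromosomes that moved together between 2 levels, found on examining the data. RAB2B (median 6215 CPM), PAN3 (4090 CPM), SLC4A1 (3106 CPM) and SENP5 (2736 CPM) belonged to it and were among the 25 most abundant genes. The set also held developmental transcription factor genes such as SOX11 and EN1. It took a median of 3.10% of counts over all 93 libraries. Among the 88 libraries, 49 had 1.37 to 24.1% and 39 had 0.118 to 0.554% (exact 95% intervals of the lowest and highest 0.113 to 0.122% and 24.0 to 24.2%). The split follows the values of the set and no label goes with it, but the column order of the deposited table does. The columns form 2 runs sorted by header, and all 39 libraries on the lower level are among the 41 columns of run 1 and all 49 on the higher level among the 52 of run 2. What the runs stand for is not stated, and no condition was read from them.

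**Figure D1:**
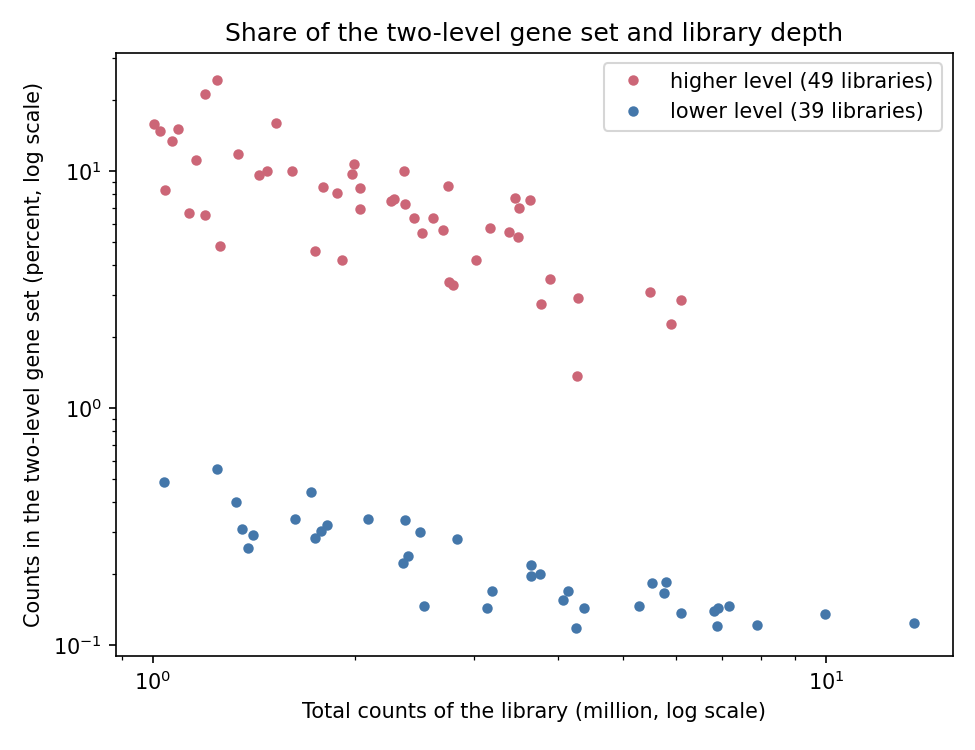
Percent of counts in the set of 83 genes (y axis, log scale) against total counts (x axis, in units of 1000000, log scale), with 1 point for each of 88 libraries. The 49 libraries on the higher level lie between 1.37 and 24.1% and the 39 on the lower level between 0.118 and 0.554%.

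The genes that differed most between libraries were mainly neutrophil granule genes and members of that set. Of the 25 genes with the largest MAD, 17 were in the set and 5 were neutrophil granule genes. Among the granule genes, AZU1 had a MAD of 3.80 on the log2 scale (median 42.8 CPM, quartiles 5.72 and 283 CPM), MPO, the myeloperoxidase gene, 3.80 (median 90.6 CPM, quartiles 12.6 and 763 CPM) and LTF, which encodes lactoferrin, 3.57 (median 201 CPM, quartiles 33.9 and 911 CPM). PRTN3 and ELANE, which encode granule proteases, had MADs of 3.79 and 3.55. The 25 also included PRG4, the lubricin gene of the synovial lining (MAD 3.79, median 65.3 CPM, highest 18933 CPM), and the neutrophil chemokine gene IL8 (MAD 3.57, median 355 CPM, highest 23889 CPM). The median MAD of the 9528 genes past the minimum was 0.65. With the set left out, a choice made after seeing the data, further granule genes (OLFM4, DEFA4, CAMP, LCN2), IL1B, OSM and the receptor gene FCGR3B entered the first 25. Several of these genes varied with the set, and so with its levels and the runs of columns: r with its member S1PR2 was 0.75 for IL8, 0.75 for IL1B, 0.73 for FCGR3B, 0.71 for OSM and -0.63 for PRG4.

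Neutrophil, antimicrobial protein and inflammatory cytokine lists were among the most variable, and the macrophage list was not. The neutrophil receptor score had a median of 5.10 and an interquartile range of 3.53 on the log2 scale, an 11.6-fold span, and all 17 members were measured. CSF3R, the receptor for granulocyte colony-stimulating factor, had a median of 326 CPM (quartiles 83.1 and 643 CPM) and the formyl peptide receptor gene FPR1 71.5 CPM (quartiles 12.1 and 146 CPM). The granule score had a median of 5.07 and an interquartile range of 4.63, a 24.8-fold span. The antimicrobial protein score, led by LYZ (median 832 CPM), S100A9 (770 CPM) and S100A8 (274 CPM), had a median of 6.28 and an interquartile range of 3.38. The inflammatory cytokine score had a median of 4.20 and an interquartile range of 2.42. The macrophage score had a median of 6.57 and a narrower interquartile range of 1.07. CD68 had a median of 657 CPM (quartiles 470 and 1024 CPM), STAB1 463 CPM and the scavenger receptor gene CD163 235 CPM.

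Among blood, lymphoid and stromal lists, the fibroblast and matrix score had the highest median, above that of the macrophage score. The erythroid score had a median of 4.83 and an interquartile range of 3.13, but its member with the highest median, SLC4A1 (3106 CPM, quartiles 42.2 and 7755 CPM), is in the 83-gene set. HBB had a median of 1792 CPM (quartiles 738 and 5646 CPM). The median scores were 2.38 for platelet, 3.65 for T cell, 2.51 for cytotoxic lymphocyte, 2.61 for B cell (whose member PAX5 is in the 83-gene set), 3.77 for plasma cell, 1.58 for dendritic cell and 1.90 for mast cell and eosinophil. Of the plasma cell list only 7 of 13 members were found, and of the T cell list 11 of 14. The fibroblast and matrix score had a median of 8.19 and an interquartile range of 1.71. Median scores were 3.63 for endothelial, 4.32 for smooth muscle and pericyte, 4.20 for synovial lining, 2.48 for cartilage, 3.31 for adipocyte, 1.66 for skeletal muscle and 1.26 for keratinocyte. Bone lists were measured too, with a median of 5.23 for osteoclast, led by TCIRG1 (842 CPM) and the collagen-degrading protease gene CTSK (319 CPM), and 3.86 for osteoblast, led by the bone sialoprotein gene IBSP (137 CPM).

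Pathway lists covered inflammation, interferon and metabolism. Median scores were 6.13 for NF-kappaB targets, 4.81 for pathogen recognition, 4.56 for type I interferon response, 4.63 for interferon gamma response, 6.54 for MHC class II and 5.75 for complement. They were 5.87 for hypoxia and glycolysis, 7.89 for lipid and lysosome, 3.06 for metallothionein, 8.54 for heme and iron, 5.63 for matrix proteases and inhibitors and 3.87 for proliferation. The interleukin 1 beta gene IL1B had a median of 55.7 CPM, and SOD2, an NF-kappaB target, 345 CPM. Of the 35 lists, 33 were coherent. The exceptions were keratinocyte (adjusted p = 0.15) and heme and iron (adjusted p = 0.18). Neutrophil granules had the highest mean correlation between members (0.91, adjusted p = 0.0012), followed by neutrophil receptors (0.84, adjusted p = 0.0012). The smallest p that 1000 random lists can give is 0.001. With the median of members as the score, median scores moved by over 1.5-fold for hypoxia and glycolysis (by 0.911 on the log2 scale), interferon gamma response (0.903), smooth muscle and pericyte (0.620), skeletal muscle (-0.738) and erythroid (-0.792).

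**Figure D2:**
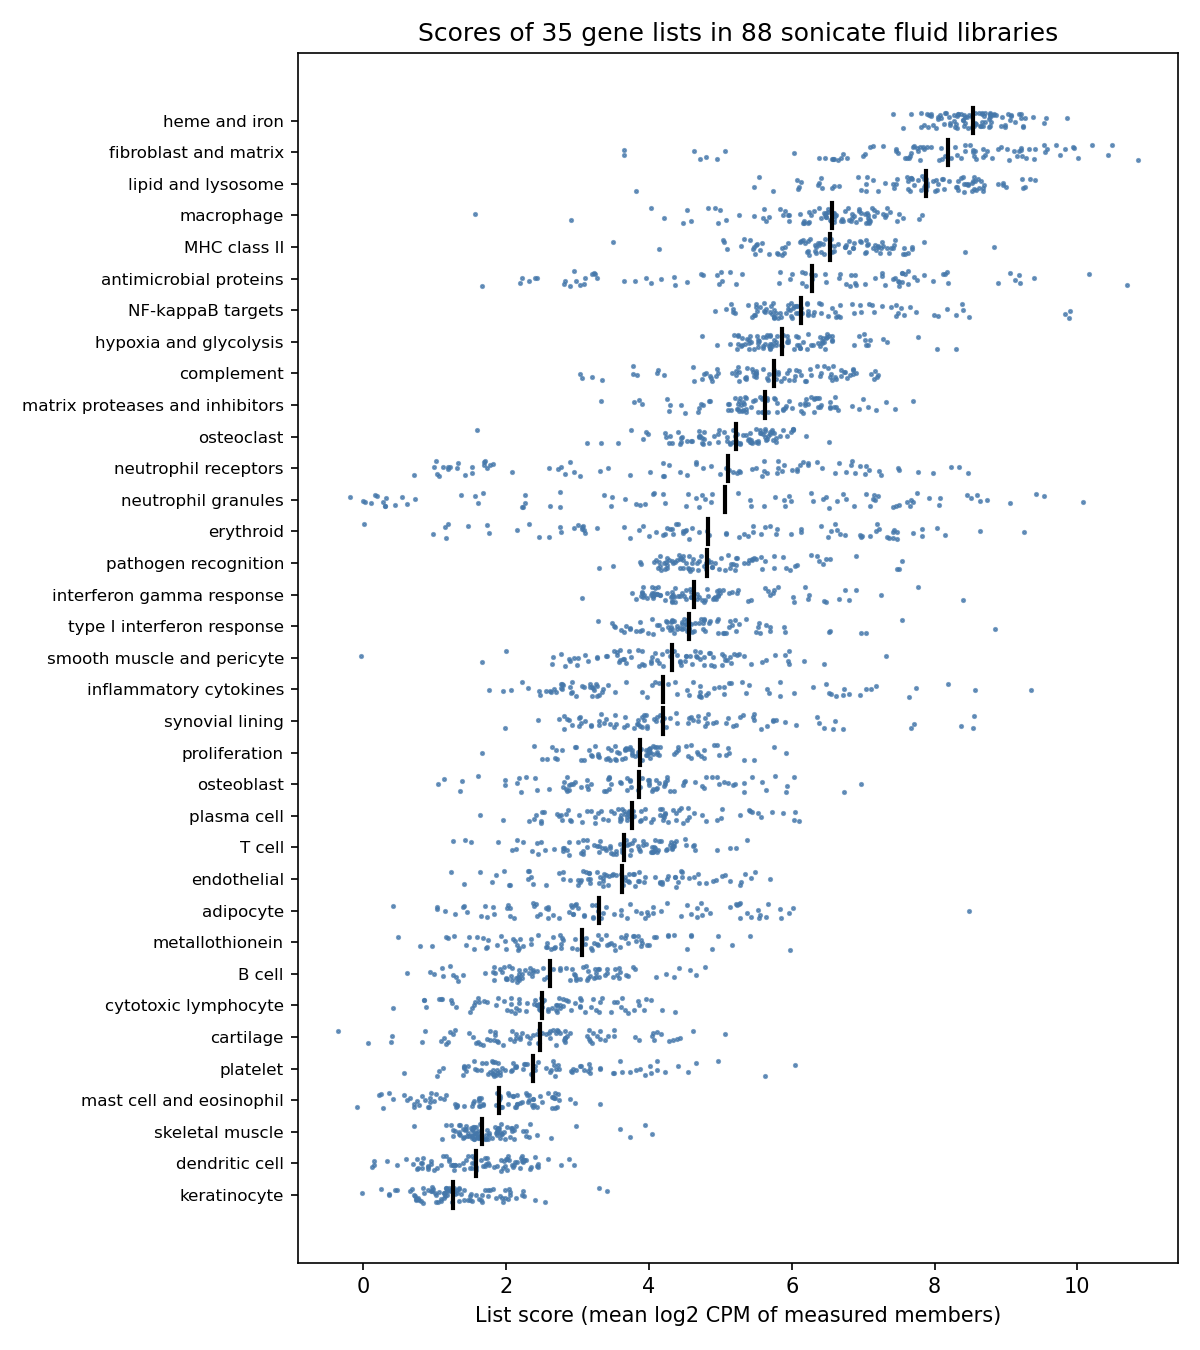
Scores of the 35 gene lists (mean log2 CPM of measured members, x axis) in 88 sonicate fluid libraries, with 1 point per library and a black bar at the median, ordered by median. Medians run from 1.26 for keratinocyte to 8.54 for heme and iron, and neutrophil granule scores run from -0.19 to 10.08.

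The relation of neutrophil transcripts to other lists was asked because neutrophils are recruited to infected joints. Neutrophil receptor scores fell into a higher cluster of 67 libraries and a lower cluster of 21, so r is given within each. The clusters overlap the levels of the 83-gene set, and so the runs of columns: 20 of the 21 are on the lower level, as are 19 of the 67, and 46 of the 51 libraries of the higher cytokine cluster are on the higher level, with 34 of the 37 of the lower on the lower. Each relation below with adjusted p = 2.6e-05 for r had an unadjusted p of 1e-05, the smallest the permutations can give, and a rho with adjusted p of 4.9e-05 or less. In the higher cluster, libraries with more neutrophil receptor transcripts had more antimicrobial protein transcripts (r = 0.83, interval 0.75 to 0.89, adjusted p = 2.6e-05, rho = 0.84, r = 0.81 without the 2 farthest libraries) and more pathogen recognition transcripts (r = 0.80, adjusted p = 2.6e-05, rho = 0.78, r = 0.80 without the 2 farthest). They also had more hypoxia and glycolysis transcripts (r = 0.61, adjusted p = 2.6e-05, rho = 0.54, r = 0.62 without the 2 farthest), whose members include the glycolytic regulator gene PFKFB3 and VEGFA. In the 50 libraries that were also in the higher cytokine cluster, inflammatory cytokines rose with neutrophil receptors (r = 0.72, adjusted p = 2.6e-05, rho = 0.71, r = 0.69 without the 2 farthest). Of 1000 random matched pairs, 1 was as far as antimicrobial proteins, 6 as far as pathogen recognition, 31 as far as hypoxia and glycolysis and 63 as far as cytokines.

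Macrophage transcripts fell as neutrophil receptor transcripts rose in the higher cluster (r = -0.60, interval -0.71 to -0.49, adjusted p = 2.6e-05, rho = -0.66, r = -0.57 without the 2 farthest). Transcripts of the osteoclast list, named for bone-resorbing relatives of macrophages, fell likewise (r = -0.60, adjusted p = 2.6e-05, rho = -0.65, r = -0.59 without the 2 farthest), as did fibroblast and matrix transcripts (r = -0.49, p = 7e-05, adjusted p = 0.00016, rho = -0.42 with adjusted p = 0.00097, r = -0.48 without the 2 farthest). Of 1000 random pairs, 1, 0 and 20 were as low. The osteoclast score also rose with the macrophage score over all 88 libraries (r = 0.77). Whether osteoclasts or macrophages gave its transcripts was not tested, so the 2 relations may not be separate. The fibroblast relation was not past the threshold in the 38 libraries of the higher cluster in the lower part by total counts (r = -0.21, adjusted p = 0.31). The osteoclast relation was not past it with summed CPM as the score (r = -0.25, adjusted p = 0.063), nor in the 6 libraries with at least 5000000 counts (r = -0.63, adjusted p = 0.19).

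Granule and receptor scores of neutrophils rose together in 67 libraries (r = 0.46, p = 0.0001, adjusted p = 0.00022, rho = 0.45 with adjusted p = 0.0004, r = 0.45 without the 2 farthest), but 539 of 1000 random pairs had an r as high, and in the 6 libraries with at least 5000000 counts there was no relation past the threshold (r = 0.0085, adjusted p = 1). Type I interferon response transcripts gave r = 0.33 (p = 0.006, adjusted p = 0.011, r = 0.36 without the 2 farthest) and rho = 0.21, not past the threshold (adjusted p = 0.14), with 749 of 1000 random pairs as high, and r was not past the threshold with library totals only (r = 0.17, adjusted p = 0.22), at least 5000000 counts (r = 0.61, adjusted p = 0.19, 6 libraries), or in the lower (r = 0.36, adjusted p = 0.05) or upper part by total counts (r = 0.32, adjusted p = 0.12). In the 19 libraries of this cluster on the lower level of the 83-gene set, chosen after seeing the data, the sign was the opposite (r = -0.67, adjusted p = 0.0046). Interferon gamma response (r = 0.25, p = 0.046, adjusted p = 0.070, rho = 0.21), T cell (r = -0.09, p = 0.45, adjusted p = 0.54, rho = -0.06) and erythroid transcripts (r = 0.26, p = 0.032, adjusted p = 0.053) were not past the threshold for r. Of 1000 random pairs, 526 were as high as interferon gamma response and 703 as high as erythroid. Only 8 were as low as T cell, whose random pairs had a median r of 0.46, so its r was low against matched lists. For erythroid transcripts rho was 0.31 (adjusted p = 0.018), and r passed in 6 of 16 alternatives, while for interferon gamma response it passed in 1 of 16, summed CPM (r = 0.45, adjusted p = 0.00031). In the lower cluster of 21 libraries, 1 relation passed, that of osteoclast transcripts (r = 0.50, p = 0.02, adjusted p = 0.036, rho = 0.48), and it rests on the 2 farthest libraries (r = 0.37, adjusted p = 0.18 without them) and passed in 9 of 15 alternatives, with 99 of 1000 random pairs as high. The other relations of that cluster had r from -0.23 for hypoxia and glycolysis to 0.45 for type I interferon response. Receptor scores in that cluster ran only from 0.71 to 2.08, near the limit for genes with no read pair in the shallower libraries. So narrow and low a range limits what a relation there can show. In combinations of clusters with 7 to 20 libraries, granules and cytokines gave r from -0.09 to 0.56 (lowest adjusted p = 0.060, permutation tests). The difference between the clusters was not tested.

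**Figure D3:**
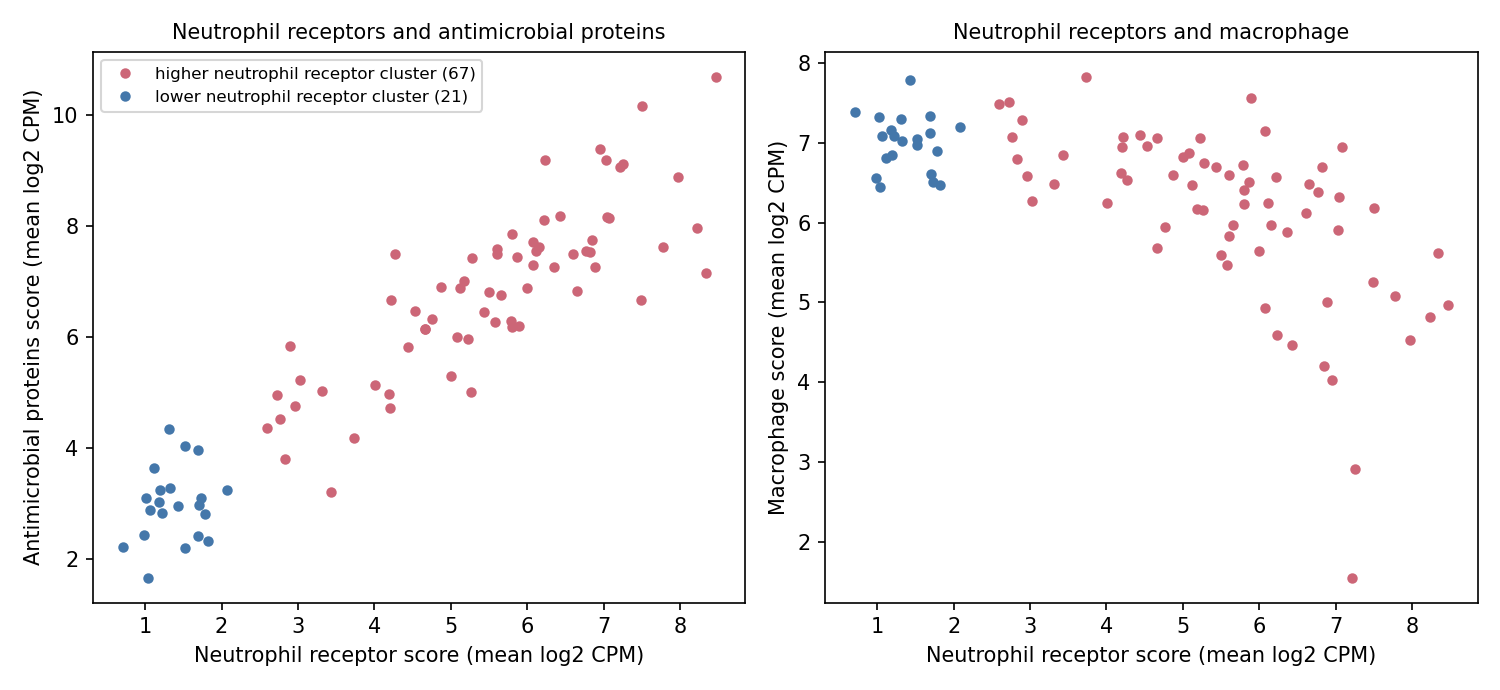
Neutrophil receptor score (x axis, mean log2 CPM) against the antimicrobial protein score (left) and the macrophage score (right), with 1 point per library in the higher cluster (67) and the lower cluster (21). In the higher cluster r is 0.83 on the left and -0.60 on the right.

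Macrophage transcripts varied with those of the MHC class II and the lipid and lysosome lists. No sort of cells is described in the labels. Such relations, like those of neutrophil receptors above, therefore cannot tell more cells of a type from a change within its cells. Over all 88 libraries the macrophage score rose with MHC class II (r = 0.82, adjusted p = 2.6e-05, rho = 0.79), led by CD74 (median 883 CPM) and HLA-DRA (473 CPM), and with lipid and lysosome genes (r = 0.92, adjusted p = 2.6e-05, rho = 0.87), among them SPP1 and the chitotriosidase gene CHIT1 (451 CPM). Osteoclast (r = 0.77, rho = 0.59), fibroblast and matrix (r = 0.71, rho = 0.65) and metallothionein transcripts (r = 0.50, rho = 0.48) rose with it too, each with adjusted p = 2.6e-05 for r. Without the 2 farthest libraries these 5 relations gave r = 0.76, 0.90, 0.65, 0.66 and 0.42, and of 1000 random pairs 2, 1, 1, 54 and 22 were as high. In the 15 libraries with at least 5000000 counts, osteoclast (r = 0.52, adjusted p = 0.12) and metallothionein transcripts (r = 0.42, adjusted p = 0.19) were not past the threshold. The heme and iron score, from a list that was not coherent, was not past the threshold (r = 0.09, p = 0.41, adjusted p = 0.51, rho = 0.22), but was with library totals only (r = 0.42, adjusted p = 7e-05), with summed CPM (r = 0.32, adjusted p = 0.0066) and in the 39 libraries on the lower level of the 83-gene set (r = 0.63, adjusted p = 8e-05). In the 15 libraries with at least 5000000 counts it gave r = -0.41, not past the threshold (adjusted p = 0.19).

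Cytokine transcripts varied with NF-kappaB targets in both cytokine clusters, the higher with 51 libraries (r = 0.90, adjusted p = 2.6e-05, rho = 0.88) and the lower with 37 (r = 0.48, p = 0.0025, adjusted p = 0.0047, rho = 0.42 with adjusted p = 0.018). Without the 2 farthest, r was 0.89 and 0.41, and of 1000 random pairs 0 and 59 were as high. In the lower cytokine cluster the relation was not past the threshold in the 12 libraries with at least 5000000 counts (r = 0.47, adjusted p = 0.19), nor in the lower (15 libraries, r = 0.56, adjusted p = 0.053) or upper part by total counts (22 libraries, r = 0.45, adjusted p = 0.059). T cell transcripts rose with cytotoxic lymphocyte (r = 0.74, adjusted p = 2.6e-05, rho = 0.69), plasma cell (r = 0.46, p = 2e-05, adjusted p = 4.9e-05, rho = 0.44) and interferon gamma response transcripts (r = 0.34, p = 0.0013, adjusted p = 0.0026, rho = 0.48). The plasma cell score rests on 7 of its 13 members and the T cell score on 11 of 14, the others not being found. No pair with the B cell list was tested. Without the 2 farthest, r was 0.71, 0.45 and 0.39. Of random pairs, 1, 150 and 252 of 1000 were as high. In the 15 libraries with at least 5000000 counts, the plasma cell (r = 0.57, adjusted p = 0.07) and interferon gamma relations (r = 0.54, adjusted p = 0.11) were not past the threshold. The interferon gamma relation was not past it either in the 44 libraries in the lower part by total counts (r = 0.34, adjusted p = 0.05) or, a choice made after seeing the data, in the 49 on the higher level of the 83-gene set (r = 0.19, adjusted p = 0.21).

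Stromal and blood lists were linked as well. Fibroblast and matrix transcripts rose with endothelial (r = 0.79, adjusted p = 2.6e-05, rho = 0.78) and with matrix protease and inhibitor transcripts (r = 0.79, adjusted p = 2.6e-05, rho = 0.78), whose members include MMP9 (median 1165 CPM) and MMP2 (180 CPM). Without the 2 farthest, r was 0.77 and 0.76, and of 1000 random pairs 0 and 1 were as high. Erythroid and platelet transcripts rose together (r = 0.78, adjusted p = 2.6e-05, rho = 0.85, r = 0.78 without the 2 farthest, 0 of 1000 random pairs as high). Osteoclast and osteoblast transcripts gave r = 0.40 (p = 0.00015, adjusted p = 0.00031, rho = 0.33 with adjusted p = 0.0033, r = 0.31 without the 2 farthest, 216 of 1000 random pairs as high), which was lost with summed CPM (r = -0.01, adjusted p = 0.98), at least 5000000 counts (r = 0.36, adjusted p = 0.25, 15 libraries) and in the lower part by total counts (r = 0.33, adjusted p = 0.05, 44 libraries). Adipocyte and skeletal muscle transcripts showed no relation past the threshold in 83 libraries (r = -0.0023, adjusted p = 0.98). In all, 21 of the 42 tests were positive, 3 negative and 18 not past the threshold, and for 14 of the 24 called fewer than 25 of 1000 random pairs were as far.

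The libraries split on the 83-gene set, and its levels are also the 2 runs of columns, so relations were repeated within the levels, a choice made after seeing the data. In the higher neutrophil cluster, antimicrobial proteins gave r = 0.78 in 48 libraries on the higher level and 0.85 in 19 on the lower level. Pathogen recognition gave 0.78 and 0.65, hypoxia and glycolysis 0.58 and 0.53, and neutrophil granules 0.50 and 0.65. Macrophage transcripts gave r = -0.57 and -0.72, osteoclast -0.59 and -0.76, and fibroblast and matrix -0.46 and -0.77. Over 49 and 39 libraries, the macrophage score gave r = 0.84 and 0.75 with MHC class II, 0.93 and 0.88 with lipid and lysosome, 0.80 and 0.51 with osteoclast, 0.75 and 0.68 with fibroblast and matrix, and 0.55 and 0.71 with metallothionein. T cell with cytotoxic lymphocyte transcripts gave 0.63 and 0.83, T cell with plasma cell 0.37 and 0.52, and erythroid with platelet 0.71 and 0.84. Fibroblast and matrix gave 0.85 and 0.73 with endothelial transcripts, and 0.83 and 0.87 with matrix proteases and inhibitors. Each of these stayed past the threshold in both levels. In the higher cytokine cluster only the higher level had enough libraries (46), where cytokines gave r = 0.71 with neutrophil receptors and 0.90 with NF-kappaB targets, and in the lower cytokine cluster only the lower level (34), where NF-kappaB targets gave r = 0.50. T cell with interferon gamma response transcripts gave r = 0.48 on the lower level (adjusted p = 0.003). Osteoclast with osteoblast transcripts gave 0.47, and 0.25 on the lower level, where it was not past it (adjusted p = 0.19).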

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

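Repeating results within the levels of the 83-gene set, with the level as a term, or without its genes, was chosen after the results were seen; the other alternatives were not. With DESeq2 size factors and with no filter on low counts, 42 of the 42 list relations kept their direction and their side of the threshold, and with depth and genes detected held fixed 41 of 41 did. The relations of neutrophil receptors with antimicrobial proteins (r 0.71 to 0.99) and with macrophages (r -0.89 to -0.52) in the higher neutrophil cluster, and of macrophages with lipid and lysosome genes (r 0.74 to 0.94), stayed past the threshold in all 16 alternatives. With at least 5000000 counts, the median total was 6088740 in 15 libraries, and 10 positive relations passed, with fewer libraries. In its higher neutrophil cluster, sonicate fluids 3, 16 and 76 were on the lower level and 24, 26 and 32 on the higher. The r of these 6 libraries can hold the difference between the levels, and so is not a test of depth alone. Relations left with under 6 libraries gave no value. Of the 25 most variable genes, 9 were shared with edgeR dispersion as the measure, the cause of which was not tested, and 8 with the set left out, which removes 17 by construction. In the lower neutrophil cluster, 1 gene, LGI2 (r = -0.84, adjusted p = 0.029), passed among 16575 genes once the filter was a count in at least 0.5 of the libraries. The relation of neutrophil receptors with type I interferon response in the higher cluster reversed to r = -0.67 (adjusted p = 0.0046) in the 19 libraries on the lower level of the set, and the cause was not tested. On the lower level, 1483 genes rose and 1387 fell with neutrophil receptors in these 19 libraries, and 2592 rose with macrophages in 39, with fewer libraries than in the pooled test, and component 1 turned to r = -0.446 with type I interferon response. Over its alternatives, the r of neutrophil receptors with type I interferon response ran from -0.67 to 0.61, with adjusted p up to 0.22. In the lower neutrophil cluster, relations not past the threshold passed in 2 of 15 alternatives for type I interferon response and in 1 each for T cell, erythroid, fibroblast and matrix, and pathogen recognition, and for granules in the libraries also in the lower granule cluster in 1 of 14. Cytokines with receptors in the higher receptor and lower cytokine clusters passed in 1 of 14. With the median of members as the score, the median scores of 4 of the 35 lists moved by more than their spread between libraries. Coherence held for 29 to 33 lists. With at least 5000000 counts the platelet, osteoclast, skeletal muscle and complement lists were also not coherent. On the higher level of the set this held for the dendritic cell and the mast cell and eosinophil lists, and on the lower for skeletal muscle. Depth limits genes below 5.97 CPM in the shallowest library.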

Other observations

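Of the tests in this part, those of the gene set with 2 levels, those within its levels, those of marrow precursors and the primary granule and nucleated erythroid lists used in the test of library depth were chosen after the results were seen, and that of the shared library total was not. Neutrophil receptor transcripts varied with many genes outside the lists in the higher neutrophil cluster of 67 libraries. Of 10597 genes, 2229 rose with the score and 3198 fell, and 43 of those that rose belong to the 83-gene set. These 43 are all the members of the set that were tested, the others being in the fixed lists or below the filter. The counts of genes that rose and fell pool both levels of the set, which are also the 2 runs of columns. In the 48 libraries on the higher level 1820 rose and 2293 fell, in the 19 on the lower level 1483 and 1387, and with the level as a term 2123 and 2900. Of the 43 set genes, 0 rose on the higher level, 4 on the lower and 6 with the level as a term. Among the highest r were those of TMEM154 (0.93, adjusted p = 1.3e-26), GLT1D1 (0.93), BASP1 (0.93), SORL1 (0.91), the transcriptional repressor gene MXD1 (0.91) and LRG1 (0.90). Among the lowest were those of TTL (the copy on chromosome 2, -0.77), FARP1 (-0.75), EPB41L2 (-0.75) and MITF, a transcription factor gene active in osteoclasts (-0.73). In the lower cluster of 21 libraries 0 genes passed after adjustment of p-values from Pearson's r (scipy), and 446 rose and 526 fell at an unadjusted p under 0.05, against 530 expected by chance in all. Receptor scores in that cluster ran only from 0.71 to 2.08. The macrophage score rose with 4527 genes and fell with 2425 over 88 libraries, with 3797 and 1688 in the 49 on the higher level and with 2592 and 2229 in the 39 on the lower. LRP1 (r = 0.90), the lysosomal protease gene LGMN (0.89) and the complement gene C2 (0.87) were among the highest, and the chromatin remodeller gene CHD7 (-0.84), the glycogen phosphorylase gene PYGL (-0.79) and the NADPH oxidase subunit gene NCF4 (-0.76) among the lowest. Each gene named here for the higher neutrophil cluster or for macrophages kept its direction and passed the threshold within both levels.

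The first 2 principal components of genes outside the lists held 35.4 and 15.6% of the variance. Of the variance of components 1 and 2, 53.0 and 23.6% lay between the levels of the 83-gene set, or runs of columns. The genes used for the components included 42 members of that set, whose values define the levels, so part of both percentages is built in. These percentages therefore do not show how far genes outside the set follow the levels. Component 1 rose with antimicrobial protein (r = 0.86) and pathogen recognition scores (r = 0.84) and fell with lipid and lysosome (r = -0.80) and macrophage scores (r = -0.76), each with adjusted p = 2.5e-05. Component 2 rose with endothelial (r = 0.76), complement (r = 0.75), osteoblast (r = 0.70) and fibroblast and matrix scores (r = 0.68), each with adjusted p = 2.5e-05. Within the higher and the lower level, component 1 gave r = 0.73 and 0.76 with antimicrobial protein, 0.76 and 0.64 with pathogen recognition, -0.82 and -0.77 with lipid and lysosome and -0.81 and -0.76 with macrophage scores, and component 2 gave 0.84 and 0.87 with endothelial, 0.81 and 0.86 with complement, 0.84 and 0.88 with osteoblast and 0.86 and 0.87 with fibroblast and matrix scores, each past the threshold. Of the 8 genes with the largest positive loadings, 7 on component 1 and 5 on component 2 were in the 83-gene set, S1PR2 first on both. The lowest loadings on component 1 were those of ITGA3, ITGBL1, HS3ST2 and TNC. Component 1 fell with log10 total counts (r = -0.40, adjusted p = 0.00019) and component 2 likewise (r = -0.30, adjusted p = 0.0066), but component 1 did not pass on the higher level (r = -0.0980, adjusted p = 0.57) nor component 2 on the lower (r = 0.0169, adjusted p = 0.94). Component 1 did pass on the lower level (r = -0.414, adjusted p = 0.013) and component 2 on the higher (r = -0.365, adjusted p = 0.016), so each relation with total counts held within 1 level. With genes detected, component 1 fell on both the higher (r = -0.494, adjusted p = 0.00083) and the lower level (r = -0.545, adjusted p = 0.00074, permutation tests). Component 2 rose with genes detected on the lower level (r = 0.342, adjusted p = 0.047) but did not pass on the higher (r = 0.277, adjusted p = 0.08).

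The set of 83 genes, with S1PR2, RAB2B, PAN3 and SOX11 among its members, lay on 2 levels (Ashman's D = 6.70 for its share of counts), which matched the 2 runs of sorted columns in 100% of 88 libraries. Differences in library total are not a sufficient account, since read pairs of the set still fell into 2 clusters (Ashman's D = 8.29). Neutrophil content alone does not give the split, since 19 of the 67 libraries of the higher neutrophil cluster were on the lower level. Of the 21 of the lower cluster, 20 were there too, so the 2 are not independent. Within the higher level the share of the set did not rise with the neutrophil receptor score (r = -0.0959, interval -0.318 to 0.168). That value concerns the spread within the level and cannot tell what separates the levels. Depth went with the spread within levels, where the share fell with log10 total counts (r = -0.762 on the higher level, -0.870 on the lower). On the higher level the slope of log2 read pairs on log2 total counts was 0.0933 (interval -0.128 to 0.314), which an amount of set reads that does not follow the total could give. That amount was not the same in each library, since read pairs of the set ranged from 29331 to 150292 on that level, beyond counting error. On the lower level the slope was 0.421 (interval 0.314 to 0.517), which excludes both a fixed amount and a fixed share as the whole account there. Whether the reads come from 1 source stays open, since the median SD of log2 ratios between members (0.768, against 1.20 for granule genes, and lower when first computed on abundant members alone) was measured on genes picked for moving together, and a library or sequencing batch cannot be told apart from any other difference that the runs of columns mark, since nothing states what they stand for and no biological explanation other than neutrophil content was tested.

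Primary granule transcripts, made in marrow before neutrophils leave it, varied with transcripts of nucleated erythroid cells among the 74 libraries of the higher granule cluster (r = 0.83, rho = 0.85, 0.85 without the 2 farthest, 0.86 in 48 on the higher level of the set and 0.81 in 26 on the lower). Their r exceeded that of neutrophil receptors with the same erythroid genes (r = 0.36) by 0.470 (interval 0.301 to 0.664), and by 0.578 (0.324 to 0.871) on the higher level, but on the lower level the difference of 0.253 had an interval that includes 0 (-0.0513 to 0.629), so marrow precursors in the fluid stay open as a candidate explanation. All 6 granule genes and 4 of the 9 erythroid genes are also in the fixed lists, and among the more abundant of both MPO had a median of 90.6 CPM and ALAS2 23.7 CPM. Depth is argued against, since r given total counts and genes detected was 0.837 (interval 0.76 to 0.90). No sort or gate that would remove marrow cells is described in the labels, and no biological explanation was tested against groups.

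Neutrophil receptor and macrophage scores were opposed in the higher neutrophil cluster (r = -0.60, and -0.57 and -0.72 within the higher and lower level of the set). Of 1000 random matched list pairs 0.1% had an r as low, which argues against a library total that acts alike on any 2 lists of that expression. The random lists were matched on expression, not on coherence. Over 88 libraries, random lists had a median correlation between members of 0.038 and 0.018, against 0.84 and 0.59 for the 2 lists. Opposition that a shared total forces between 2 coherent lists therefore stays open. A varying mixture of cell types stays open and was not tested, and so does any condition of the implants, since the labels give none.

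The share of the 83-gene set lay on 2 levels, and each library's value is as follows. The exact 95% interval of each share is within 4.67% of its value, for counting error only. On the lower level, sonicate fluids 2, 3, 4, 6, 7, 8, 10 and 11 had 0.195, 0.135, 0.257, 0.320, 0.341, 0.487, 0.335 and 0.340%. Sonicate fluids 12, 13, 15, 16, 37, 58, 59 and 60 had 0.184, 0.124, 0.200, 0.167, 0.281, 0.444, 0.554 and 0.168%. Sonicate fluids 61, 62, 63, 64, 66, 67, 69 and 71 had 0.293, 0.146, 0.121, 0.137, 0.302, 0.169, 0.144 and 0.222%. Sonicate fluids 72, 73, 76, 77, 78, 79, 80 and 81 had 0.283, 0.121, 0.140, 0.30, 0.218, 0.147, 0.146 and 0.155%. Sonicate fluids 82, 85, 86, 88, 89, 90 and 91 had 0.143, 0.118, 0.309, 0.143, 0.402, 0.183 and 0.237%. On the higher level, sonicate fluids 5, 9, 14, 17, 18, 19, 21 and 22 had 5.26, 5.76, 9.74, 9.67, 8.30, 3.49, 11.1 and 8.54%. Sonicate fluids 23, 24, 25, 26, 27, 28, 29 and 30 had 7.65, 2.85, 3.41, 2.27, 7.26, 2.90, 10.7 and 5.51%. Sonicate fluids 31, 32, 33, 34, 35, 36, 38 and 39 had 15.0, 3.10, 6.32, 6.98, 6.93, 3.30, 4.84 and 6.31%. Sonicate fluids 40, 41, 42, 43, 44, 45, 46 and 47 had 7.56, 5.49, 5.66, 1.37, 8.06, 4.61, 4.20 and 6.51%. Sonicate fluids 48, 49, 50, 51, 53, 54, 55 and 56 had 11.8, 15.8, 4.20, 8.51, 9.98, 13.4, 14.8 and 7.46%. Sonicate fluids 57, 68, 70, 74, 75, 83, 84 and 87 had 2.74, 10.0, 24.1, 10.1, 21.2, 15.9, 6.67 and 7.67%. Sonicate fluid 93 had 8.67%.

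Neutrophil receptor scores fell into clusters of 67 and 21 libraries, with each library's mean log2 CPM as follows. Sonicate fluids 2, 3, 4, 5, 6, 7, 8 and 9 had 0.99, 2.72, 1.73, 6.15, 1.19, 2.96, 4.76 and 5.61. Sonicate fluids 10, 11, 12, 13, 14, 15, 16 and 17 had 4.87, 1.11, 1.78, 1.71, 3.43, 3.03, 2.60 and 5.08. Sonicate fluids 18, 19, 21, 22, 23, 24, 25 and 26 had 4.67, 6.85, 7.03, 6.36, 6.61, 8.23, 4.20 and 6.66. Sonicate fluids 27, 28, 29, 30, 31, 32, 33 and 34 had 7.51, 5.23, 5.80, 4.53, 7.22, 5.44, 4.01 and 7.08. Sonicate fluids 35, 36, 37, 38, 39, 40, 41 and 42 had 6.23, 5.66, 8.35, 8.47, 7.04, 2.08, 5.86 and 5.81. Sonicate fluids 43, 44, 45, 46, 47, 48, 49 and 50 had 6.76, 4.27, 6.89, 4.20, 5.89, 5.00, 6.43 and 7.25. Sonicate fluids 51, 53, 54, 55, 56, 57, 58 and 59 had 5.79, 5.26, 6.22, 6.95, 7.49, 7.97, 6.08 and 6.11. Sonicate fluids 60, 61, 62, 63, 64, 66, 67 and 68 had 1.32, 3.31, 1.43, 0.71, 1.02, 6.00, 1.69 and 5.18. Sonicate fluids 69, 70, 71, 72, 73, 74, 75 and 76 had 1.52, 5.27, 4.66, 1.52, 1.22, 5.61, 6.83 and 2.77. Sonicate fluids 77, 78, 79, 80, 81, 82, 83 and 84 had 5.12, 5.50, 1.06, 2.83, 4.44, 3.74, 7.78 and 6.07. Sonicate fluids 85, 86, 87, 88, 89, 90, 91 and 93 had 1.33, 2.89, 5.58, 1.18, 1.69, 1.82, 1.04 and 4.21.

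Neutrophil granule scores fell into clusters of 74 and 14, with each library's mean log2 CPM as follows. Sonicate fluids 2, 3, 4, 5, 6, 7, 8 and 9 had -0.19, 4.66, 1.37, 6.48, 0.44, 5.61, 7.69 and 7.50. Sonicate fluids 10, 11, 12, 13, 14, 15, 16 and 17 had 8.07, 0.31, 0.55, 2.27, 2.24, 4.89, 4.74 and 4.70. Sonicate fluids 18, 19, 21, 22, 23, 24, 25 and 26 had 3.66, 7.42, 7.67, 5.90, 6.44, 5.43, 3.46 and 2.76. Sonicate fluids 27, 28, 29, 30, 31, 32, 33 and 34 had 8.60, 3.49, 8.46, 3.82, 6.87, 4.23, 1.56 and 5.97. Sonicate fluids 35, 36, 37, 38, 39, 40, 41 and 42 had 9.53, 6.64, 5.90, 7.21, 7.93, 0.62, 7.17 and 6.27. Sonicate fluids 43, 44, 45, 46, 47, 48, 49 and 50 had 5.24, 7.46, 7.65, 2.75, 5.42, 4.06, 8.74 and 10.08. Sonicate fluids 51, 53, 54, 55, 56, 57, 58 and 59 had 4.55, 3.94, 7.14, 9.42, 4.20, 4.52, 9.06 and 8.64. Sonicate fluids 60, 61, 62, 63, 64, 66, 67 and 68 had 3.38, 5.76, 0.72, 0.03, 1.60, 8.51, 0.16 and 7.61. Sonicate fluids 69, 70, 71, 72, 73, 74, 75 and 76 had 0.10, 6.53, 7.10, 2.61, -0.00, 7.15, 6.30 and 3.88. Sonicate fluids 77, 78, 79, 80, 81, 82, 83 and 84 had 8.06, 7.75, 0.31, 2.27, 7.05, 1.68, 6.76 and 5.99. Sonicate fluids 85, 86, 87, 88, 89, 90, 91 and 93 had 0.27, 4.87, 6.72, 0.20, 4.07, 2.22, 0.30 and 4.79.

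Inflammatory cytokine scores fell into clusters of 51 and 37, with each library's mean log2 CPM as follows. Sonicate fluids 2, 3, 4, 5, 6, 7, 8 and 9 had 3.52, 2.62, 1.76, 5.83, 3.30, 2.67, 3.09 and 4.72. Sonicate fluids 10, 11, 12, 13, 14, 15, 16 and 17 had 3.28, 2.31, 2.07, 2.69, 4.08, 2.98, 3.28 and 4.39. Sonicate fluids 18, 19, 21, 22, 23, 24, 25 and 26 had 4.62, 7.05, 8.57, 5.68, 6.73, 8.18, 4.70 and 5.05. Sonicate fluids 27, 28, 29, 30, 31, 32, 33 and 34 had 6.95, 5.05, 4.27, 4.72, 7.18, 6.61, 5.65 and 6.30. Sonicate fluids 35, 36, 37, 38, 39, 40, 41 and 42 had 4.56, 5.40, 6.81, 9.36, 5.36, 2.80, 6.03 and 4.82. Sonicate fluids 43, 44, 45, 46, 47, 48, 49 and 50 had 7.64, 4.14, 3.98, 4.72, 4.98, 3.91, 4.91 and 3.34. Sonicate fluids 51, 53, 54, 55, 56, 57, 58 and 59 had 5.16, 4.80, 4.73, 5.83, 7.11, 7.74, 3.26 and 2.92. Sonicate fluids 60, 61, 62, 63, 64, 66, 67 and 68 had 2.45, 3.18, 2.56, 2.61, 2.48, 2.77, 2.92 and 3.20. Sonicate fluids 69, 70, 71, 72, 73, 74, 75 and 76 had 2.78, 5.30, 2.91, 3.36, 3.42, 6.55, 6.48 and 3.21. Sonicate fluids 77, 78, 79, 80, 81, 82, 83 and 84 had 3.20, 3.68, 1.95, 3.23, 4.04, 4.37, 6.52 and 6.71. Sonicate fluids 85, 86, 87, 88, 89, 90, 91 and 93 had 3.06, 3.18, 4.53, 2.89, 2.22, 2.78, 2.77 and 5.12.

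Skeletal muscle scores fell into clusters of 5 and 83, with each library's mean log2 CPM as follows. Sonicate fluids 2, 3, 4, 5, 6, 7, 8 and 9 had 1.72, 1.34, 1.93, 1.86, 1.88, 1.77, 1.26 and 3.94. Sonicate fluids 10, 11, 12, 13, 14, 15, 16 and 17 had 1.10, 1.36, 1.63, 1.61, 2.98, 1.87, 1.55 and 1.52. Sonicate fluids 18, 19, 21, 22, 23, 24, 25 and 26 had 1.56, 1.90, 1.55, 1.86, 1.94, 1.87, 1.91 and 1.52. Sonicate fluids 27, 28, 29, 30, 31, 32, 33 and 34 had 2.08, 4.04, 1.85, 2.12, 0.70, 2.06, 1.42 and 1.65. Sonicate fluids 35, 36, 37, 38, 39, 40, 41 and 42 had 1.57, 1.45, 1.80, 2.33, 2.27, 2.01, 2.24 and 1.54. Sonicate fluids 43, 44, 45, 46, 47, 48, 49 and 50 had 1.75, 1.60, 3.60, 1.61, 1.66, 1.35, 2.33 and 1.91. Sonicate fluids 51, 53, 54, 55, 56, 57, 58 and 59 had 1.41, 2.08, 1.75, 2.62, 1.55, 2.06, 1.62 and 1.28. Sonicate fluids 60, 61, 62, 63, 64, 66, 67 and 68 had 1.59, 1.16, 1.35, 1.54, 1.40, 2.13, 1.23 and 1.66. Sonicate fluids 69, 70, 71, 72, 73, 74, 75 and 76 had 1.53, 1.93, 1.62, 1.74, 1.49, 2.43, 1.72 and 1.40. Sonicate fluids 77, 78, 79, 80, 81, 82, 83 and 84 had 1.51, 1.89, 1.26, 1.99, 1.46, 1.44, 3.73 and 1.33. Sonicate fluids 85, 86, 87, 88, 89, 90, 91 and 93 had 1.71, 1.61, 2.28, 1.57, 1.98, 1.43, 1.52 and 2.11.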
